A study of Mus musculus with 3 samples.

How the data were processed

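DNase-seq, in which the enzyme DNase I cuts accessible DNA and the cut ends are sequenced, was carried out on kidney tissue of female B6CASTF1/J mice, the F1 cross of C57BL/6J and CAST/EiJ, at 14 days of age. The series holds 3 libraries in 1 group, numbered as biological replicates 1, 2 and 3 in the labels. Library 1 came from the biosample labelled with number 6, whereas libraries 2 and 3 both carry the biosample with number 5. Each biosample label names 3 females, and whether their kidneys were pooled is not given in the sources used here. An SD over the 3 libraries therefore mixes the spread between 2 biosamples with the spread between libraries of 1 biosample.

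Per the deposited README files, each library's peaks, footprints and false discovery rates were made from its own alignments to mm10, so nothing was pooled over libraries. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. It is likewise not given whether CAST/EiJ variants were taken into account in the alignment to a C57BL/6J reference, which is a limit on every count below. For each library the authors deposited 2 narrow-peak lists with a signal value per peak. The unit of that deposited signal is not stated, but in each library 100% of the values were whole multiples of a single step within a tolerance of 0.05 steps, and the steps were 0.00549, 0.00222 and 0.00391 in libraries 1, 2 and 3. If the step is 1 read scaled to the library's total, the relative depths are 1, 2.47 and 1.40, and the read totals themselves are not known. The signal was used mainly to rank peaks within a list, and its values were compared only within a library. The authors also deposited intervals with a false discovery rate, a kind of q-value, with intervals under 0.05 listed. Footprints, short stretches protected from cutting inside accessible DNA, were deposited as intervals with the constant 0.01 in the score column, whose meaning is not stated, and no other score.

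The smallest listed false discovery rate inside each peak was taken with bedtools 2.31.1. Its highest value over peaks was 0.0500, 0.0500 and 0.0499 in the longer lists and 0.000994, 0.001 and 0.000992 in the shorter lists, so the lists correspond to thresholds of 0.05 and 0.001. By a rule set before the data were examined, the longer list was used throughout, and the shorter one as an alternative. The reference was GRCm38, which is mm10, with GENCODE mouse release 21 annotation. All peaks lay within the lengths of the reference chromosomes. All 311 genes of the 23 gene lists were found in the annotation by symbol, and 6 of them stand in more than 1 list.

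Peaks of different libraries were counted as shared when they overlapped by at least 1 bp, and the base-pair Jaccard index was computed for each pair of libraries. A peak was counted at a start site when its midpoint lay within 1 kb of any annotated transcription start site, and as distal otherwise. The share of such peaks was set against 100 random placements on sequenced bases of the same chromosomes, with a one-sided permutation p whose smallest possible value is 0.0099. A gene was counted as having an accessible promoter when a peak overlapped the 1 kb on either side of any of its start sites. Whether a start site of another gene lay nearer to the peak was not taken into account. For gene lists, the mean over the 3 libraries was compared with 10000 random lists of protein-coding genes, drawn with replacement and matched on the number of CpG dinucleotides in the 1 kb centred on the 5′ end of the gene, in 10 bins. Distal peaks were counted within the gene body extended by 25 kb on both sides, and those random lists were matched on extended length. Both tests were two-sided permutation tests with Benjamini-Hochberg adjustment over the 23 lists, and the smallest p they can give is 0.0002. They compare a list with other genes in these libraries and do not measure the spread between animals. Gene lists, consensus strings of 24 motifs and the rule for named genes were set before the data were examined. Of each list the rule takes up to 4 members with a promoter peak in the most libraries, ordered by the strength of that peak, and up to 2 in the fewest libraries, plus 18 genes of the kidney and controls and the 5 strongest shared peaks. Some genes and strings that these rules name are not reported here. Strength is given as the percentile of the peak's signal within its own list.

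Motif matches were exact matches to a consensus string on either strand. For each footprint inside a peak, a window of the same width was drawn at random in the same peak outside footprints, and the log2 ratio of the 2 counts was taken after adding 0.5 to each. Fisher's exact test was run per library with Benjamini-Hochberg adjustment over motifs, and a motif was called only when all 3 libraries passed 0.05 in the same direction. Footprints with a motif at their border and motifs longer than most footprints are undercounted in this way. Peak densities were computed per Mb of sequenced bases. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and Y chromosome sequences were searched in the rest of the genome with minimap2 2.31.

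The list test was tested on simulated data. With promoters drawn at the observed share of each CpG bin, 0.8% of 500 random lists of 15 genes had p below 0.05, and 93.5% of 200 lists of 15 CpG-poor genes with 90% of members open were called. With ties counted as 0.5, the first share was 3%, so ties account for part of its distance from 5%. The list test made fewer such calls than its threshold allows. The share of 93.5% holds for CpG-poor genes only. The alternatives tried were the shorter peak list, the stronger 50% of each list, equal numbers of top-ranked peaks, a stricter overlap, other windows, other matching, other backgrounds for motifs and each library left out in turn. Some more were added after seeing the data and are named as such in the closing section.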

Results

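DNase I accessibility was measured in kidney tissue of 14-day-old female mice of the B6CASTF1/J cross in 3 libraries. All 3 belong to 1 group, so the data hold no contrast between conditions. What they allow is a description of accessible chromatin in this tissue, with the spread between libraries as its error, and a comparison of the pair of libraries from the shared biosample with the other pairs. Read totals were not used here. If the steps of the signal values stand for 1 scaled read each, library 2 was the deepest, at 2.47 times library 1, and library 3 lay between them at 1.40 times.

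Library 1 held 209140 accessible regions, library 2 held 255682 and library 3 held 135585, which gives 200136 ± 60553 (SD, n = 3). They covered 37.9, 50.3 and 26.4 Mb, and the median region was 180 bp wide in each library. The counts did not follow the steps of the signal: library 3 had fewer regions than library 1. Footprints numbered 555219, 692361 and 405773 in libraries 1, 2 and 3, or 551118 ± 143338 (SD, n = 3), with a median width of 11 or 12 bp. Between 84.4% and 87.7% of footprints lay in a listed region. The authors' shorter lists, at a false discovery rate of 0.001, held 135902, 151660 and 80609 regions.

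Regions of library 3, which held the fewest, were found in the others more often than the reverse. Of its regions, 86.4% overlapped one of library 2 and 78.5% one of library 1, whereas 45.8% of library 2 and 51.1% of library 1 were found in library 3. Libraries 1 and 2 shared 66.9% of the regions of library 1 and 54.6% of those of library 2. These differences in direction went with the lengths of the lists. With equal numbers of top-ranked regions the shares were 67.3% both ways for libraries 1 and 3. For libraries 2 and 3 they were 73.9% of library 2 and 74.1% of library 3. The base-pair Jaccard index was 36.2% for libraries 1 and 2, 37.4% for libraries 1 and 3, and 37.9% for libraries 2 and 3, which come from the shared biosample. That pair exceeded the mean of the other pairs by 1.07 percentage points, against an SD of 0.842 over the 3 pairs. With the stronger 50% of each list the difference turned to -1.35 percentage points, so the pair from the shared biosample could not be set apart from the others. No pair of libraries held identical lists.

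Stronger regions recurred more often. Each list was ranked by signal and divided into 5 groups of equal size. Of the strongest group, 97.2% ± 1.15 (SD, n = 3) was found in both of the other libraries, and of the weakest group 16.3% ± 16.9 (SD, n = 3). The weakest group of library 2 recurred in 0.481% of cases, that of library 1 in 14.3% and that of library 3 in 34.2%. In all, 102275 regions of library 1, 102319 of library 2 and 101953 of library 3 were found in all 3 libraries. The gap between the strongest and weakest group was 80.8 ± 15.9 percentage points (SD, n = 3).

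**Figure D1:**
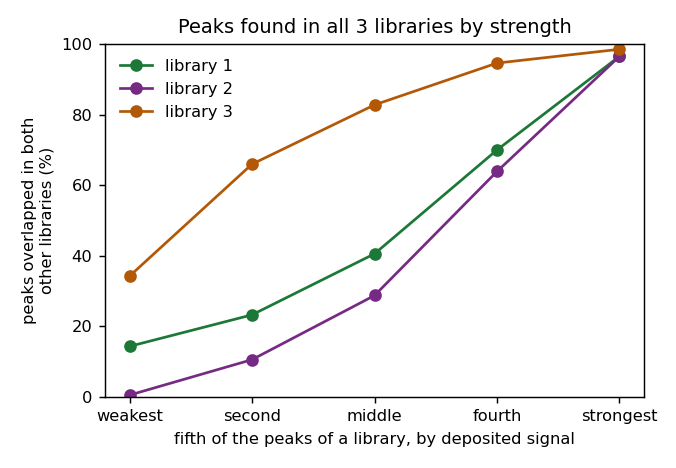
Share of the regions of each library that overlapped a region in both of the other libraries (percent, y axis), by 5 equal groups of deposited signal (x axis), with 1 line per library. In the strongest group the libraries lie between 96.5% and 98.5%, and in the weakest group between 0.481% and 34.2%.

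Accessible regions were concentrated at transcription start sites. In libraries 1, 2 and 3, 23.9%, 22.8% and 31.8% of regions had their midpoint within 1 kb of an annotated start site, against 6.33%, 6.34% and 6.35% of random placements. The enrichment was 4.12-fold ± 0.764 (SD, n = 3), with the smallest one-sided permutation p that 100 placements can give, 0.0099, in each library. A further 35.7% ± 3.47 of regions lay in introns, 32.4% ± 2.05 between genes and 5.73% ± 1.15 in exons (SD, n = 3). Regions at start sites were found in all 3 libraries in 68.8% ± 10.1 of cases and those in introns in 51.6% ± 22.1 (SD, n = 3), with start-site regions ahead in each of the libraries. Of 21728 protein-coding genes outside the Y chromosome, 73.6%, 75.2% and 72.1% had an accessible promoter in libraries 1, 2 and 3, and 15234 genes had one in all 3.

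Genes of the nephron tubule had accessible promoters more often than genes of like CpG content. Of the 25 proximal tubule genes, 89.3% ± 10.1 (SD, n = 3) had a promoter peak, against 61.1% in matched random lists (permutation test, p = 0.0004, adjusted p = 0.00307), and 20 had one in all 3 libraries. The strongest were at Slc6a19, a neutral amino acid transporter, Ass1, the argininosuccinate synthase, Lrp2, which encodes the endocytic receptor megalin, and Aqp1, a water channel, with mean strength percentiles of 94.4, 93.9, 90.6 and 90.2. The Lrp2 peak of library 1 (mm10 chromosome 2, 69586021 to 69586220) spanned the annotated 5′ end of the gene. Slc34a1, the sodium-phosphate cotransporter of the brush border, had a promoter peak at percentile 82.4 ± 6.32 (SD, n = 3). The peaks at Slc6a19 and Slc34a1 lay 12105 to 12205 and 1434 to 1454 bp from the 5′ end of the gene, at other annotated start sites. Kap and Slc22a8, an organic anion transporter, had a promoter peak in 1 library each.

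All 14 thick ascending limb genes had a promoter peak in all 3 libraries, that is 100% against 68.8% at random (permutation test, p = 0.0004, adjusted p = 0.00307). Among the strongest were those at Egf (percentile 97.2 ± 0.746) and the transcription factor gene Irx2 (84.6 ± 6.29; SD, n = 3). The peak at Egf (chromosome 3, 129725041 to 129725200 in library 1) lay at a start site inside the gene, far from its 5′ end. Umod, which encodes uromodulin, reached percentile 63.6 ± 18.95 and Slc12a1, the cotransporter blocked by loop diuretics, 56.4 ± 14.2 (SD, n = 3). Of the 10 genes of the distal convoluted and connecting tubule, 96.7% ± 5.77 (SD, n = 3) had a promoter peak against 65.4% at random (permutation test, p = 0.0018, adjusted p = 0.0104). Wnk4 and Klhl3, regulators of salt transport, had percentiles of 90.8 and 86.8, and the calcium handling genes Calb1 and Slc8a1 78.5 and 75.7. Slc12a3, the thiazide-sensitive cotransporter, was at 68.5 ± 23.9 (SD, n = 3), and Klk1 lacked a promoter peak in 1 library. The peak at Slc8a1 lay 67957 to 68097 bp from the 5′ end. That at Slc12a3 lay 24880 and 24860 bp from it in libraries 1 and 2, and that at Umod 1702 bp in library 3.

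Endothelial and stromal genes stood above random lists as well. All 15 endothelial genes had a promoter peak in all 3 libraries (100% against 77.5%; permutation test, p = 0.008, adjusted p = 0.0307), with Esam, Ehd3, the VEGF receptor gene Kdr and Egfl7 the strongest at percentiles of 92.9, 92.4, 91.4 and 89.7. Of 15 stromal and mural genes, 93.3% ± 6.67 (SD, n = 3) had one against 65.7% (permutation test, p = 0.0062, adjusted p = 0.0285). Col1a1, a collagen gene, Pdgfra, Tagln and Meis1 led this list at 97.9, 93.8, 90.6 and 89.7, whereas Ren1, which encodes renin, had a promoter peak in 1 library and Lum in 2. The peaks at Esam and Egfl7, and that at Pdgfra in libraries 2 and 3, lay over 1 kb from the 5′ end, as did that at Ren1. The calls of the 5 lists above random depended on the peaks and the start sites used. With the authors' shorter peak lists none passed the adjusted threshold (adjusted p from 0.0672 to 0.286 by permutation), although 4 of the 5 had an unadjusted permutation p between 0.0142 and 0.0254. The shares there were 74.7% against 54.3% at random for the proximal tubule, 85.7% against 62.15% for the thick ascending limb and 76.7% against 59.5% for the distal convoluted and connecting tubule. They were 93.3% against 71.0% for endothelium and 84.4% against 58.8% for stroma and mural cells. Over all 11 alternatives the adjusted permutation p ranged from 0.0023 to 0.0862 for the proximal tubule, from 0.0046 to 0.0834 for the thick ascending limb and from 0.0069 to 0.960 for the distal convoluted and connecting tubule. The ranges were 0.0184 to 0.231 for endothelium and 0.0023 to 0.264 for stroma and mural cells. The endothelial and stromal calls were also lost without library 1, at adjusted permutation p of 0.0561 and 0.0698, and without library 3, at 0.0652 and 0.0515. The excess stayed about as large: without library 1 the shares were 100% against 77.5% and 90% against 65.35%, and without library 3 they were 100% against 78.7% and 93.3% against 67.4%. With 1 start site per gene, an alternative added after seeing the data, endothelium was at 86.7% against 71.1% (adjusted permutation p = 0.231). The distal convoluted and connecting tubule was at 86.7% against 59.1% (adjusted permutation p = 0.0515). The proximal tubule, thick ascending limb and stromal lists kept their calls there.

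Other kidney lists did not pass the test. All 23 kidney transcription factor genes (87.4% at random; permutation test, adjusted p = 0.062), all 12 podocyte genes (89.0%; 0.290) and all 10 nephron progenitor genes (90.5%; 0.468) had a promoter peak in all 3 libraries, but their matched random lists were high as well. A share of 100% is the highest possible. At that share the unadjusted permutation p was 0.215 for podocyte genes and 0.447 for progenitor genes. No outcome could have called either list above random, so their failure to pass does not show that an excess is absent. With 1 start site per gene the transcription factor list fell to 84.1% against 83.9% at random and the podocyte list to 86.1% against 86.0%. The progenitor list stayed at 100% against 88% there. Among the transcription factor genes Esrra, Tfcp2l1, Maf and Emx2 had the strongest peaks, at percentiles of 99.95, 97.1, 94.97 and 94.1. Pax8 reached 93.7 ± 2.31, Hnf4a 86.0 ± 6.93 and Pax2 85.4 ± 4.65 (SD, n = 3). The strongest promoter peak of Hnf4a (chromosome 2, 163547001 to 163547200 in library 1) lay at a start site inside the gene. In podocyte genes, Synpo, Cdkn1c and Podxl were among the strongest at 94.2, 94.0 and 88.6. Nphs1, which encodes nephrin of the slit diaphragm, was at 79.7 ± 8.88, and Wt1 was at 76.7 ± 8.53 (SD, n = 3). The peaks at Synpo and Nphs1 lay 10922 and 26026 bp from the 5′ end, at other annotated start sites. The progenitor genes Six2 and Cited1 had promoter peaks at 65.6 ± 4.63 and 64.3 ± 8.48 (SD, n = 3), below Osr1 at 88.5 and Lhx1 at 88.0.

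In the collecting duct, 91.7% of the 12 principal cell genes had a promoter peak in each library (72.8% at random; permutation test, adjusted p = 0.134), led by Tfcp2l1, the sodium channel subunit gene Scnn1g, Elf5 and Aqp3 at percentiles of 97.1, 92.6, 85.4 and 81.1. The exception was Aqp2, the vasopressin-regulated water channel (chromosome 15, 99579055 to 99584547). Its promoter had no listed peak in any library, although 7, 8 and 4 distal peaks lay in the gene or within 25 kb of it. Of the 12 intercalated cell genes, 80.6% ± 4.81 (SD, n = 3) had a promoter peak (56.7% at random; permutation test, adjusted p = 0.116). Rhcg, Rhbg, Atp6v0a4 and Slc4a9 had the strongest, and Foxi1, a transcription factor gene of this cell type, was at percentile 37.98 ± 18.95 (SD, n = 3). The peaks at Elf5, Rhcg and Slc4a9 lay 13053 to 34193, 22477 to 22497 and 1714 bp from the 5′ end. Aqp6 had none in any library and the proton pump gene Atp6v1g3 had one in 1 library.

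**Figure D2:**
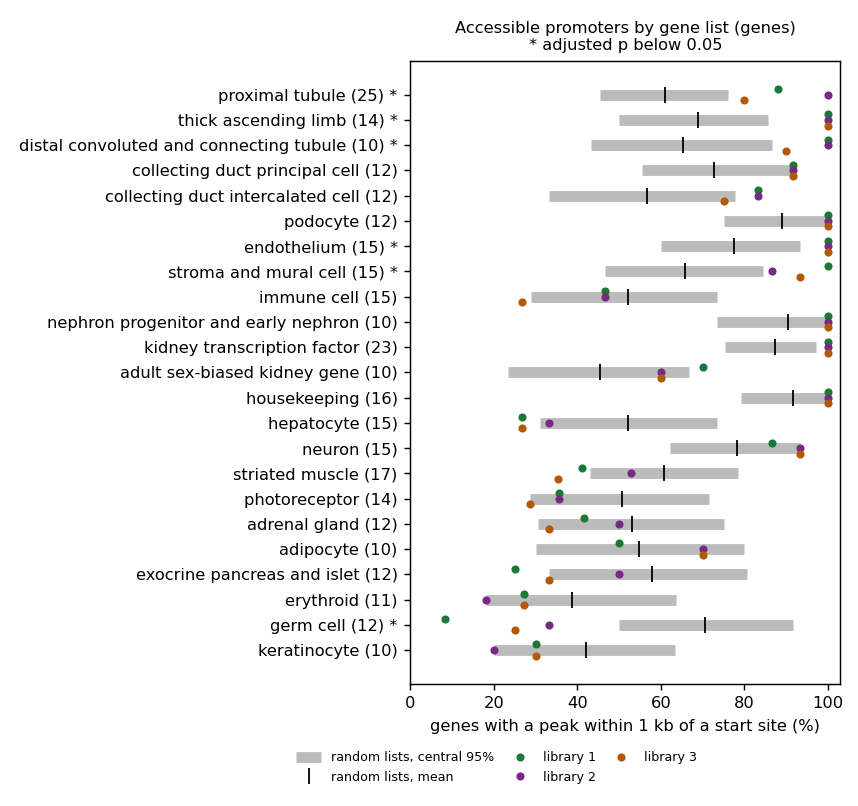
Percent of the genes of each list with a peak within 1 kb of a start site (x axis), 1 point per library, with the central 95% (grey bars) and the mean (ticks) of 10000 random lists matched on CpG content. The thick ascending limb and endothelial lists are at 100% in all 3 libraries, and the germ cell list is below its random range in all 3.

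Genes of other tissues served as a reference. The germ cell list was the 1 list called below random: 22.2% ± 12.7 (SD, n = 3) of its 12 genes had a promoter peak against 70.7% (adjusted p = 0.00307, unadjusted 0.0002, the smallest the permutation test can give). Prm1 and Prm2, the protamines, had none in any library, whereas Dazl had one in all 3 at percentile 93.5. The hepatocyte list was at 28.9% ± 3.85 (SD, n = 3) against 52.2% (permutation test, adjusted p = 0.116), with no promoter peak at Alb, which encodes albumin, or Ahsg, and peaks in all 3 libraries at Apoh and Itih1. Striated muscle (43.1% against 60.9%), photoreceptor (33.3% against 50.6%), exocrine pancreas and islet (36.1% against 57.8%), erythroid (24.2% against 38.8%), adrenal gland (41.7% against 53.0%), keratinocyte (26.7% against 42.2%) and immune cell genes (40% against 52.2%) had values below their random means, without passing the test (adjusted p from 0.159 to 0.428 by permutation). Neuronal (91.1% against 78.2%), adipocyte (63.3% against 54.8%) and adult sex-biased kidney genes (63.3% against 45.5%) had values above it and did not pass either (adjusted p from 0.196 to 0.552 by permutation). All 16 housekeeping genes had promoter peaks in all 3 libraries, with Ywhaz, Rplp0, Actb and Ppia at percentiles above 99.3 (that at Ywhaz over 1 kb from the 5′ end), but their random lists were at 91.7% (permutation test, adjusted p = 0.3002). The unadjusted permutation p was 0.235 at this highest possible share, so the housekeeping list could not have been called above random.

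Distal regions did not set any list apart. None of the 23 lists passed the adjusted threshold in the permutation test on distal peaks per gene. At an unadjusted permutation p under 0.05 there were 3 higher and 4 lower lists. The higher ones were thick ascending limb genes, with 11.7 ± 7.74 distal peaks per gene (SD, n = 3) against 7.28 at random, endothelial genes, with 15.4 ± 5.78 against 10.1, and kidney transcription factor genes, with 15.4 ± 5.60 against 10.2. The lower ones were hepatocyte (3.84 ± 1.57 against 6.85), erythroid (2.82 ± 0.808 against 6.00), keratinocyte (2.27 ± 0.551 against 5.46) and adult sex-biased kidney genes (5.43 ± 2.16 against 10.3; SD, n = 3). The smallest adjusted p was 0.112. Library 2 carried the value of the thick ascending limb, which without it was 7.39 against 5.87 (permutation p = 0.238). Without library 2 the hepatocyte, keratinocyte and adult sex-biased lists were no longer under 0.05 either, at permutation p of 0.117, 0.0682 and 0.119, and without library 1 the endothelial list was not, at 0.0916. The values stayed on the same side: 3.77 against 5.485 for hepatocyte, 2.25 against 4.265 for keratinocyte and 5.35 against 8.56 for sex-biased genes. The endothelial list was at 14.2 against 9.84. Pax2 had 32, 38 and 21 distal peaks in libraries 1, 2 and 3 and Pax8 had 23, 45 and 13.

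Footprints held matches to the strings of several factors far more often than the rest of the same regions. The string of the insulator protein CTCF was found in 0.861% of footprints and 0.00169% of free windows, a log2 ratio of 8.94 ± 0.33 (SD, n = 3). The strings of NFI and NRF1 had log2 ratios of 9.31 ± 0.32 and 6.44 ± 0.58, and those of RFX, CREB/ATF, SP/KLF and the USF/MITF E-box 5.17 ± 0.24, 5.02 ± 0.33, 4.90 ± 0.54 and 4.86 ± 0.25 (SD, n = 3). NFI and RFX had no match in the free windows of any library, so their ratios depend on the added 0.5. That of HNF1, below, does too, with 1, 0 and 0 matches in the free windows of libraries 1, 2 and 3. The NEUROD E-box, YY1 and ETS/GABPA followed at 1.96, 1.40 and 0.74. These 10 strings were higher in footprints of all 3 libraries (Fisher's exact test, largest adjusted p = 0.0014). Some forms of the CTCF string contain the whole NEUROD E-box string, so a footprint with such a form counts for both. How many footprints held both was not counted. The ratio of the NEUROD E-box therefore does not show which factor was bound. HNF1 and HNF4, factors of the kidney tubule and liver, had log2 ratios of 3.81 ± 0.89 and 1.09 ± 0.73 (SD, n = 3). They passed in libraries 1 and 2 but not in library 3, where adjusted p was 0.333 and 0.520 by Fisher's exact test. Without library 3, both and the half-site of ESRR were called. With windows shifted by 50 bp, RFX and ETS/GABPA were no longer called (adjusted p of 0.353 and 0.0522 by Fisher's exact test). The log2 ratio of ETS/GABPA was 0.81 ± 0.26 there against 0.74 ± 0.34 (SD, n = 3), and fewer of the footprints compared held the string, 0.0425% against 0.0974%. RFX again had no match in free windows. In distal footprints ETS/GABPA and YY1 were not called (0.766 and 0.787 by Fisher's exact test), at log2 ratios of 0.58 ± 0.52 and 1.16 ± 1.87 (SD, n = 3). The shifted windows gave smaller log2 ratios for CTCF, NFI, SP/KLF and CREB/ATF, at 7.03, 7.77, 4.04 and 4.16. Those of the USF/MITF E-box, RFX, the NEUROD E-box and HNF1 were smaller too, at 4.28, 3.23, 1.82 and 1.42. NRF1 was nearly unchanged at 6.435, and YY1 was higher at 2.12.

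The strings of 7 factors were lower in footprints than in free windows in all 3 libraries (Fisher's exact test, largest adjusted p = 0.0132). FOX and GATA had the lowest log2 ratios, at -2.73 ± 0.34 and -2.29 ± 0.20, followed by PU.1, CRX/OTX, TEAD, AP-1 and NF-Y at -1.69, -1.14, -0.79, -0.67 and -0.26 (SD, n = 3). Shuffled strings of the same letters, a comparison added after seeing the data, also departed from 0. They gave -2.09 for GATA, -1.76 for TEAD and 4.38 for SP/KLF, and 2 of the 7 strings, FOX and CRX/OTX, stayed below their shuffled strings in all 3 libraries. With windows shifted by 50 bp, AP-1, NF-Y, PU.1 and CRX/OTX were no longer called (adjusted p of 0.275, 0.998, 0.868 and 0.501 by Fisher's exact test), at log2 ratios of -0.44, -0.05, -1.25 and -0.72. In distal footprints NF-Y, TEAD, PU.1 and CRX/OTX were not (0.172, 0.0692, 0.297 and 0.126 by Fisher's exact test), at -0.15, -0.70, -1.58 and -0.98, so those of TEAD, PU.1 and CRX/OTX stayed near their values in all footprints. FOX alone was lower in these 3 comparisons, at -2.32 with shifted windows and -2.65 in distal footprints. Of the 10 higher strings, 9 stayed above their shuffled strings in all 3 libraries. YY1 was the exception, with a difference of -0.79 on the log2 scale from its shuffled strings. For RFX, 1 of the 9, the shuffled strings had a log2 ratio of 0 with an SD of 0, as strings without any match would. Its comparison therefore adds nothing to its ratio. HNF1, HNF4, the nuclear receptor half-site of ESRR, GRHL/TFCP2, MEF2 and the MYOD E-box were not called. Of these, HNF1 and HNF4 lay above their shuffled strings in all 3 libraries, by 4.99 ± 0.41 and 2.27 ± 0.54 on the log2 scale (SD, n = 3). The value of HNF1 again rests on the added 0.5. The others differed in direction between libraries.

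**Figure D3:**
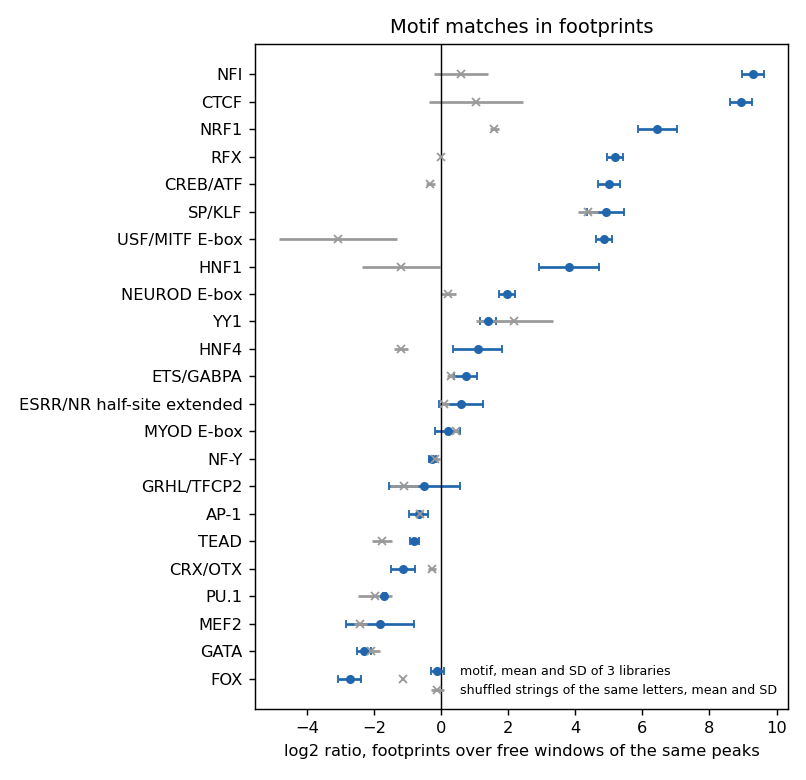
Log2 ratio of motif matches in footprints over same-width free windows of the same regions (x axis) for the consensus strings, as mean and SD of 3 libraries (circles) beside shuffled strings of the same letters (crosses). NFI and CTCF lie highest at 9.31 and 8.94, and FOX lies lowest at -2.73.

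Start-site regions held more footprints than distal ones. They held 3.10 ± 0.271 footprints per region against 2.19 ± 0.117 in distal regions (SD, n = 3), a ratio of 1.42 ± 0.138 (SD, n = 3) that was above 1 in all 3 libraries. In the strongest of the 5 groups by signal, start-site regions held 4.76 ± 0.266 and distal ones 3.85 ± 0.108 (SD, n = 3), with the start-site regions ahead in all 3 libraries. In the 3 middle groups distal regions were ahead in all 3 libraries, and in the weakest group the libraries differed in direction. In the group next to the strongest, start-site regions held 2.99 ± 0.342 against 3.21 ± 0.281, and in the middle group 2.05 ± 0.196 against 2.29 ± 0.227 (SD, n = 3). Per 100 bp, start-site regions of the strongest group held 2.04 ± 0.124 and distal ones 2.02 ± 0.0764 (SD, n = 3), with start-site regions ahead in library 1 only and distal regions ahead in libraries 2 and 3. In the 3 middle groups distal regions held more per 100 bp in all 3 libraries, at 1.54 ± 0.149 against 1.10 ± 0.0535 in the group next to the strongest (SD, n = 3).

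The X chromosome was sparse in accessible regions. It held 31.2, 42.3 and 23.6 regions per Mb in libraries 1, 2 and 3, against 85.1, 104 and 55.0 on the autosomes together, a ratio of 0.401 ± 0.0322 (SD, n = 3). The lowest autosomes held 66.7, 82.2 and 43.0 per Mb, chromosome 3 in libraries 1 and 3 and chromosome 16 in library 2. Chromosome 11 held the most in each library, at 123, 147.5 and 84.9. X has fewer protein-coding genes per Mb than the autosomes, at 5.80 against 8.67. Their promoters were accessible in 55.9% ± 2.14 of cases on X and in 74.4% ± 1.56 on the autosomes (SD, n = 3). Autosomal genes weighted to the CpG content of X genes were at 69.2% ± 2.26 (SD, n = 3). The ratio of peak densities was 0.268 with the stronger 50% of each list.

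**Figure D4:**
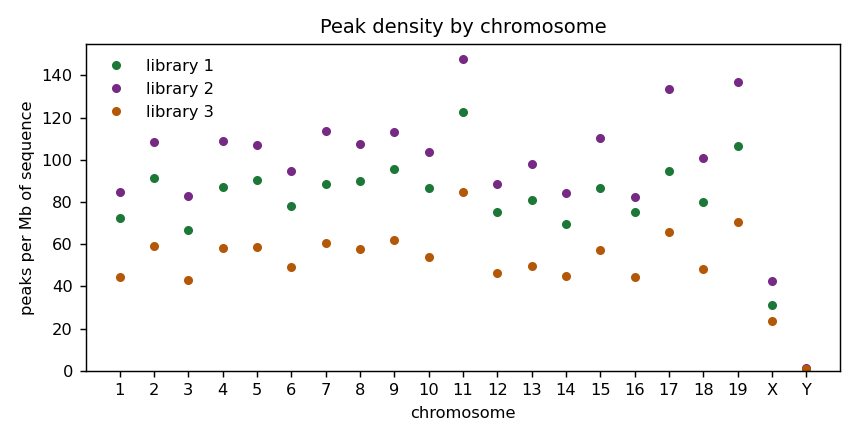
Accessible regions per Mb of sequenced bases (y axis, linear) on each chromosome (x axis), with 1 point per library. X lies below every autosome in each library, at 31.2, 42.3 and 23.6 per Mb in libraries 1, 2 and 3, and Y at 0.522, 1.48 and 0.851.

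HOX genes, which pattern the body axis, were accessible across all clusters. Of the 39 genes, 94.0% ± 6.45 (SD, n = 3) had a promoter peak. Among all protein-coding genes outside Y the shares were 73.6%, 75.2% and 72.1% in libraries 1, 2 and 3. No random lists matched on CpG content were drawn for HOX genes, so an excess over such genes was not tested. Such lists were at 87.4% for kidney transcription factor genes and 90.5% for nephron progenitor genes. Hoxd3 and Hoxd4 had equal strengths in each library, as did Hoxc5 and Hoxc10, so 1 peak may count for more than 1 gene. All genes of paralogue numbers 1, 3 to 7 and 9 to 11 had one in all 3 libraries. Of the 4 genes of number 13, 2, 4 and 3 had one in libraries 1, 2 and 3, and of the 2 genes of number 12, 1, 2 and 1 had one. Hoxa2 and Hoxb8 each lacked one in library 1. Hoxa10 reached strength percentiles of 98.2, 97.6 and 95.4 and Hoxd10 94.7, 94.0 and 87.3, whereas Hoxd13 was at 23.0, 71.7 and 47.6. These HOX genes were chosen for mention after their values were seen.

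The strongest regions found in all 3 libraries lay at 5 places. The first was between genes on X (143482981 to 143483140), 35531 bp from the start of Pak3. The next was in an exon of Lars2 on chromosome 9 (123461921 to 123462080). The others were at start sites, at Dynlt1b on chromosome 17 (6430021 to 6430180), at the long noncoding gene Gm42418 on chromosome 17 (39846781 to 39846900) and at Mplkip on chromosome 13 (17694881 to 17695060). These names are of the nearest start, and the regions lay over Gm26848, CT010467.1 and Sugct, in that order. The signals of the 5 regions in library 1 were 90, 58.0, 68.4, 45.5 and 45.8, in the authors' units, against a median of 0.620 over all regions of that library. No list of regions with artificially high signal was applied here. Whether reads from repeated sequence raised these signals was not tested.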

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

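Both tests below were set before their results were seen, but the comparison with random Y windows and the count of each Y place once were added after the share of Y peaks with copies was known. Peaks were listed on the Y chromosome although all libraries are labelled female: 46 in library 1, 130 in library 2 and 75 in library 3. No comparison above is made on Y by itself, although totals, shares and the densities per chromosome include these peaks. Male DNA in the libraries would open promoters of single-copy Y genes, and 0 of the 4 tested (Kdm5d, Uty, Ddx3y and Eif2s3y) had a peak within 1 kb of a start site in any library, which argues against it. Reads from copies elsewhere in the genome are a candidate explanation: 59.4% of the 251 Y peaks (95% Wilson interval 53.2% to 65.2%) had a copy outside Y of at least 90% identity over at least 90% of the length, against 40.4% of 1000 random Y windows of the same widths (37.4% to 43.5%). The 251 peaks count a place up to 3 times. With overlapping peaks counted once, 63.1% of 168 places had a copy (55.6% to 70.0%), and without library 2 55.1% of 89 (44.7% to 65.0%). The lower end of the latter interval is just above the upper end for the random windows. The share of peaks was 56.5%, 65.4% and 50.7% in libraries 1, 2 and 3. At the end of Y taken as the pseudoautosomal region, which females carry on X, lay 13, 26 and 15 of the peaks, and 24.1% of these 54 had a copy, against 69.0% of the 197 before it. Sequence shared with X should have had a copy there, so 24.1% conflicts with that label. The search may have missed copies or the end may be misplaced, which was not tested. All shares with a copy carry this limit. The 9, 27 and 25 peaks before that end without a copy stay unexplained. No biological explanation was tested.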

How the results depend on the processing

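The alternatives without dense 10 kb windows, with 1 start site per gene, with the wider 50% of footprints, against shuffled strings, with the stronger 50% for the gap between strong and weak regions and with equal numbers of peaks for the X chromosome were chosen after seeing the data; the others were set before. The enrichment at start sites (2.65-fold to 5.63-fold), the gap between strong and weak regions (67.7 to 82.7 percentage points) and the numbers of footprints kept their direction under each alternative run. Peaks per library fell to 122724 in the shorter lists and 100265 in the stronger 50%, by construction. The pair from the shared biosample differed in Jaccard index from the others by 2.41 percentage points in the shorter lists, 5.61 with equal numbers, 2.52 without dense windows and -1.35 in the stronger 50%, and in peaks found by -0.85 in the stronger 50%; the cause was not tested. Peaks found in the other library averaged 63.9%, 75.9% in the stronger 50%, 72.8% with equal numbers, 53.5% when 50% of both peaks had to overlap, and 60.7% to 66.1% with a library left out. Lists with accessible promoters above random numbered 5, against 0 with the shorter lists (4 of the 5 at an unadjusted permutation p under 0.05), 1 with the stronger 50%, 3 with equal numbers, 3 with 1 start site per gene and 3 to 5 with a library left out; lists below numbered 1, against 3 with windows of 500 bp, 2 with 2.5 kb and 9 with unmatched random lists, which leave CpG content uncorrected. The germ cell list passed under all 11 alternatives (adjusted p from 0.0023 to 0.023 by permutation), the thick ascending limb under 9, the proximal tubule under 8, the distal convoluted and connecting tubule under 6, endothelium under 6 and stroma and mural cells under 5. Distal lists numbered 0 in both directions (3 higher and 4 lower at an unadjusted permutation p under 0.05), and 1 higher and 2 lower with unmatched lists, where gene length is uncorrected. Strings higher in footprints numbered 10, against 9 with windows shifted by 50 bp (RFX and ETS/GABPA lost, the MYOD E-box gained), 8 in distal footprints (ETS/GABPA and YY1 lost), 9 against shuffled strings and 10 to 13 with a library left out. Strings lower in footprints numbered 7, against 3 with windows shifted by 50 bp, 3 in distal footprints and 2 against shuffled strings, where YY1 turned to -0.79 and TEAD to 0.97 on the log2 scale; the cause was not tested. The footprint ratio was 1.57 with 500 bp, the X ratio 0.268 in the stronger 50%, 0.343 in the shorter lists and 0.315 with equal numbers, and 84.6% of HOX genes were accessible in the shorter lists; the cause was not tested. Values of single lists that were not called moved or changed sign in 7 promoter and 22 distal comparisons, and those of motifs in 5. A sign change was counted as a reversal only where the value was called in either setting, a rule set before these values were seen. The stricter set of footprints was not run, because the footprints carry no score. Leaving a library out leaves no comparison of pairs. No paired analysis was possible because the series holds 1 group. The read depth behind a missing peak is unknown, so a region not listed is not shown to be closed.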

Other observations

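The tests of sequencing depth, of a low local background, of detection at the same signal rank and of the dense windows of each library were chosen after the results had been seen. The comparison within bands of false discovery rate and that of equal numbers of peaks were set before their results were seen.

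Some genes best known from other tissues had strong promoter peaks in all 3 libraries. Lipe, which encodes hormone-sensitive lipase, was at strength percentile 99.3 ± 0.099, Chga, a granule protein gene of the adrenal medulla, at 97.2 ± 0.859 and Actn3 of fast muscle at 96.6 ± 2.13 (SD, n = 3). Apoh of hepatocytes was at 96.3 ± 1.02, Gnat1 of rods at 95.4 ± 3.07, Dazl of germ cells at 93.5 ± 2.75 and Krt10 of keratinocytes at 93.1 ± 3.00 (SD, n = 3). The peaks at Lipe, Gnat1 and Krt10 lay over 1 kb from the 5′ end of the gene, at other annotated start sites. Those at Apoh, Actn3 and Dazl lay 507 to 547, 632 to 652 and 676 to 716 bp from the 5′ end. Whether a start site of a neighbouring gene lay nearer was not tested. These peaks therefore need not be promoters of the genes named. None of the lists these genes come from was called above random. Other members of these and similar lists, such as Myh1, Myh2, Adipoq, Cidec, Cnga1, Cyp11a1, Cyp11b2, Ivl, Alas2 and Gata1, had no promoter peak in any library. The immune genes Cd14, Cd68 and Lyz2 had promoter peaks in all 3 libraries, and Adgre1 and C1qa in none.

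Library 2 held fields of weak peaks. Windows of 10 kb with 15 or more peaks, a definition chosen after seeing the data and after another one based on runs of weak peaks, numbered 1279 in library 2, 24 in library 1 and 83 in library 3, and held 8.68%, 0.185% and 1.03% of the peaks. Loci of Pkhd1, the gene of recessive polycystic kidney disease, and Stk32b, chosen from the 10 genes with the largest excess after their values were seen, had 106 and 126 distal peaks in library 2 against 14 and 18 in library 1 and 16 and 11 in library 3. Chromatin open across these loci in the shared biosample stays open as an explanation. Within bands of false discovery rate, dense peaks of library 2 were found in library 3 less often than its other peaks, by a difference of -44.4 percentage points, but dense peaks of a band had 0.132 to 0.520 of the signal of the others, so this comparison mixes in their weakness. At the same signal rank the difference was -10.9 percentage points (95% normal interval -11.6 to -10.2) over the 16 of 20 bins in which over 10% of the other peaks were found, and -5.50 over all 20. This interval and those below count each peak as independent, although the 22183 dense peaks of library 2 lay in 1279 windows. They leave out the spread between windows and between libraries. These windows were picked for being dense in library 2, and few were dense in library 3, so a deficit there partly restates the pattern. With the 83 windows of library 3 the difference was 1.95 (-0.124 to 4.02) for peaks found in library 2 and -31.1 (-32.7 to -29.45) for those found in library 1, and 55 of the 83 were dense in library 2. Dense peaks of library 2 were also found in library 1 less often than its other peaks, at -23.9. In bin 10, though, 19.4% of the dense peaks were found in library 1 and 17.9% in library 3, against 57.6% and 35.9% of the others. Library 3 held more of the dense peaks than library 1 in the other bins, except in bins 15 and 16. Of the 24 dense windows of library 1, 17 were also dense in library 2 and 7 in library 3. With the 24 windows of library 1 the differences were 16.75 and 14.95 for libraries 2 and 3. Biosample and library cannot be told apart here. A low local background in the peak calling stays open: peaks in the windows passed at 0.261 of the signal of other library 2 peaks in the same band (median over 6 bands), but the windows were first noticed for their weak peaks, so a lower signal restates that. Sequencing depth stays open: library 2 had 8.75 times the windows that a proportion to depth gives, but such counts need not grow in proportion, and the growth from library 1 to library 3 carried on to library 2 would give 659.6 windows, against which it had 1.94 times as many.

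The pair of libraries from the shared biosample had the highest Jaccard index by a small margin. Different numbers of peaks could have produced this. With equal numbers of top-ranked peaks that pair was still ahead of the next pair, by 1.02 percentage points, but the other pairs differed by more than that from each other, at 50.2% and 41.0%. The values do not decide, and a true difference between biosamples, of which there are 2, cannot be told apart from differences between libraries.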
